A study of Mus musculus with 9 samples.

How the data were processed

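The deposited table held 15134 genes by 9 libraries as signal values (normalised counts), which the authors had made as reads divided by a size factor for each library. Per the submitters' processing notes, Salmon and DESeq2 were used with the mouse genome GRCm39, and no versions were given. The values of every library were whole multiples of a single step to within 1e-06 (largest offset 5.2e-10), so reads could be recovered by division. The recovered reads were used for library depth and for the count models only. Hippocampus had been taken as micro-punches, and libraries had been made from 800 ng of total RNA by oligo(dT) selection and random priming. Strandedness was not stated. Raw reads were not used here.

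Values were tested as log2 of the normalised count plus 1, and genes with a mean of at least 10 were kept, which removed 44 genes and left 15090. Every gene of the deposited table had at least 5 reads in at least 8 of the 9 libraries. Genes without reads in more libraries than that allows are therefore absent from all counts. List members missing from the table are not in the list counts either. Linear models with 1 mean per group were fitted by limma 3.58.1 with an intensity trend in R 4.3.3. P-values were adjusted by the Benjamini-Hochberg method, and an adjusted p under 0.05 was called a change, "rose" or "fell". An F test covered all 3 groups. A gene was said to have moved back when it was called in 5xFAD vehicle against nTg vehicle and called in the opposite direction in JW-65 against 5xFAD vehicle. Of 42 gene lists written from general knowledge of cell types and pathways, 41 had at least 3 tested genes and were tested by camera with a correlation between genes of 0.01, by camera with an estimated correlation, and by fry. Counts adjusted over the list alone come from the limma p-values of the list members. Count models were fitted to the recovered reads with edgeR 4.0.16 and DESeq2 1.42.0, and figures were drawn with matplotlib 3.10.9. The smallest exact p that a permutation of 3 against 3 libraries can give is 0.1, so no permutation test of single genes was run.

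The genes considered for naming were the 12 largest rises and the 12 largest falls of each comparison among called genes with a mean of at least 50 in the higher group and no overlap between the libraries of the 2 groups, predicted genes excluded. App, Psen1, Thy1 and Trpc3 were always named, and up to 4 members among those with the smallest p-values were named for the lists described. A selection of these genes is named, and other genes named are Hbb-bs and genes carried over from another comparison. Values are given as mean ± SD with n = 3 libraries per group. The comparisons, the filter, the scale, the lists and the alternatives other than those named as added later were fixed before the data were examined. GC content, transcript length and gene type came from GENCODE M21 on GRCm38 by gene identifier, which matched 99.9% of the tested genes, and no coordinates were used. Parents of retrocopies were found by comparing transcript sequences of the same annotation.

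In a self-test with changes put into simulated data of the same size, 1.5-fold, 2-fold and 4-fold changes were recovered for 26.9%, 64.2% and 93.9% of changed genes in 5xFAD vehicle against nTg vehicle. The shares were 25.4%, 61.2% and 80.3% in JW-65 against 5xFAD vehicle and 25.4%, 61.2% and 84.8% in JW-65 against nTg vehicle. Unchanged genes were called 6, 6 and 10 times among 15090. A shifted list was called in all 3 comparisons and 0 of 39 other lists were. The simulated genes were independent, so this does not show how often lists of correlated genes are called wrongly. The held-out shift was 0.2% where 0% had been put in and 38.3% where 40% had been put in. With the 40% shift, 1 gene was called as moved back among 2000 genes changed 2-fold. The held-out shift and the count of genes moved back therefore need not go together.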

Results

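Messenger RNA of the mouse hippocampus was profiled in 9 libraries. Of these, 3 came from nTg mice given vehicle, 3 from 5xFAD mice given vehicle and 3 from 5xFAD mice given JW-65. The 5xFAD line carries mutant human APP and PSEN1 transgenes under a neuronal Thy1 promoter and serves as a model of Alzheimer's disease. JW-65 is an antagonist of TRPC3, a calcium-permeable cation channel. It was given intraperitoneally at 20 mg/kg, 3 times a week for 1 month, to 5xFAD mice that were 12 months old. The ages of the mice given vehicle were not stated. The table held 15134 genes, and the reads assigned to them numbered 17897466, 23610694 and 23233780 in the nTg libraries. They numbered 26338518, 22520306 and 23927310 in the 5xFAD vehicle libraries and 31231441, 29491414 and 21105840 in the 5xFAD JW-65 libraries. The labels did not state that the libraries of a group came from separate animals, so p-values measure only the spread between these samples.

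The first principal component of the log2 values took 37.3% of the variance. It placed the nTg libraries at -37.1, -44.9 and -42.6, the 5xFAD vehicle libraries at 50.8, 21 and 39.7, and the JW-65 libraries at 1.8, 10.7 and 0.7. The Y-linked genes Kdm5d and Uty stood high in 5xFAD vehicle 1, at 675.5 and 179.9 normalised reads, and in 5xFAD JW-65 1, at 576.9 and 297. In the other 7 libraries Kdm5d lay between 25.7 and 98.4 and Uty between 8.1 and 35.9. None of the nTg libraries stood high, so the level of these genes was not balanced between the genotypes. Sex was not included in the main fits, and a difference in sex between libraries was not tested. Ttr, the main transcript of the choroid plexus, ranged from 478.6 to 23509 and was highest in nTg vehicle 1, 5xFAD vehicle 1 (22198) and 5xFAD JW-65 2 (22077). Haemoglobin transcripts varied within groups, with Hbb-bs at 513 ± 544 (SD, n = 3) in nTg, 1326 ± 1056 in 5xFAD vehicle and 242 ± 157 in JW-65.

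Transcripts counted at App, Psen1 and Thy1 were higher in 5xFAD than in nTg hippocampus, and those at App and Psen1 were higher again under JW-65. App (ENSMUSG00000022892), the amyloid precursor gene, stood at 40406 ± 1107 normalised reads (SD, n = 3) in nTg, 63139 ± 5839 in 5xFAD vehicle and 97586 ± 4113 in 5xFAD JW-65. The App change was 0.64 on the log2 scale between the vehicle groups (limma, adjusted p = 0.00123) and 0.63 between JW-65 and vehicle (adjusted p = 0.011). Psen1 (ENSMUSG00000019969), a subunit of the gamma-secretase complex, rose from 1329 ± 55.5 to 2544 ± 89.1 between the vehicle groups (log2 0.94, adjusted p = 5.34e-05) and reached 3634 ± 93.8 under JW-65 (log2 0.51, adjusted p = 0.0102). Thy1 (ENSMUSG00000032011), the gene whose promoter drives the transgenes, rose from 11922 ± 276 to 57457 ± 7730.0 (log2 2.26, adjusted p = 2.19e-06). It was 61624 ± 5687 under JW-65, a difference from vehicle that did not pass (log2 0.11, 95% interval -0.14 to 0.35, adjusted p = 0.584). The table gives a single value per gene and does not separate human from mouse transcripts. Trpc3 (ENSMUSG00000027716), the gene of the drug target, was 139.5 ± 11.6 in nTg, 194 ± 36 in 5xFAD vehicle and 113 ± 13.2 under JW-65. Trpc3 fell under JW-65 relative to vehicle (log2 -0.76, adjusted p = 0.043), while 5xFAD vehicle against nTg (log2 0.46, adjusted p = 0.112) and JW-65 against nTg (log2 -0.30, adjusted p = 0.414) did not pass. The Trpc3 call ended when any library except 5xFAD vehicle 2 was left out. The log2 changes then lay between -0.85 and -0.61 and the adjusted p between 0.0592 and 0.131. It also ended after quantile normalization, when only the groups compared were fitted, and with replicate number as a block. The same held with Ttr or Kdm5d as a covariate and without both libraries high in Kdm5d. Over all alternatives the Trpc3 log2 change lay between -0.85 and -0.51. Without 5xFAD vehicle 1 and 3 together the JW-65 call of Psen1 ended as well (adjusted p = 0.0677, log2 0.43 to 0.54 over the alternatives), while that of App did not.

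**Figure D1:**
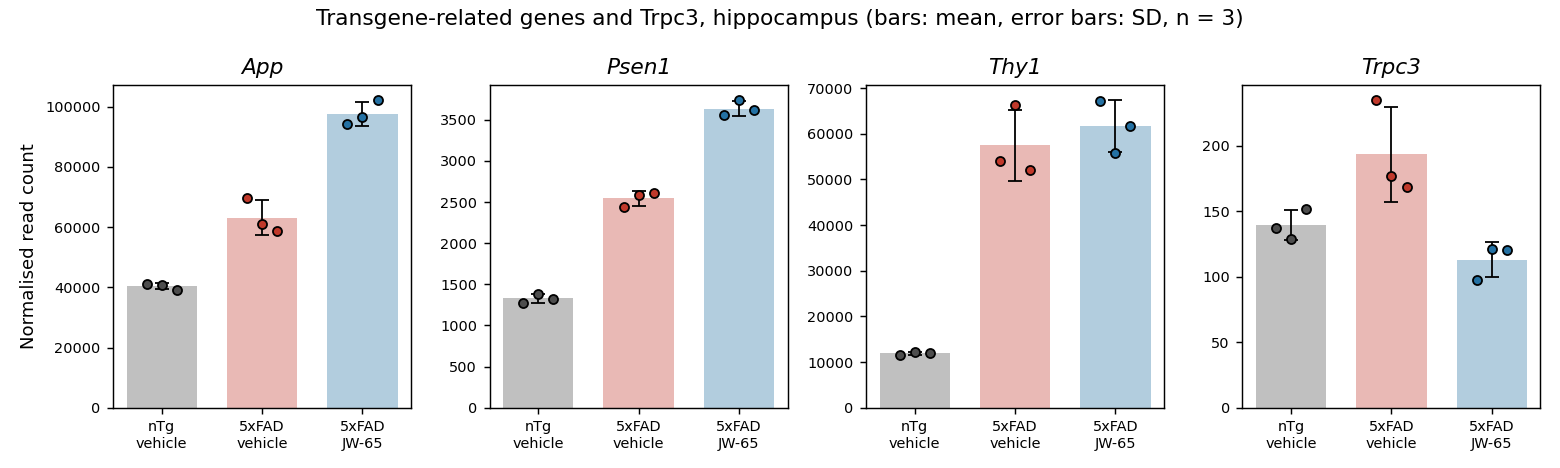
Normalised read counts of App, Psen1, Thy1 and Trpc3 in each library (points), with the group mean (bars, axes starting at 0) and SD (error bars, n = 3). The JW-65 libraries lie above all other libraries for App and Psen1, overlap with 5xFAD vehicle for Thy1 and lie below 5xFAD vehicle for Trpc3.

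The comparison of 5xFAD with nTg mice under vehicle shows how the 2 genotypes differed without treatment. Many microglial, reactive astrocyte, complement, antigen-presentation, interferon and lysosomal genes were higher in 5xFAD. C4b (ENSMUSG00000073418), a complement component, rose 11.968-fold, from 1599 ± 187 to 19194 ± 2678 normalised reads (SD, n = 3, adjusted p = 1.33e-07). Gfap (ENSMUSG00000020932), the intermediate filament of astrocytes, rose 6.24-fold, from 11765 ± 1089.5 to 75225 ± 21727 (adjusted p = 1.75e-05). Itgax (ENSMUSG00000030789), an integrin of plaque-associated microglia, had the largest rise of the named genes, from 10.9 ± 12.3 to 459 ± 324 (log2 5.98, 4.66 to 6.99 over the alternatives, adjusted p = 0.00175). Of 15090 genes tested, 4249 changed, of which 2048 rose and 2201 fell, and 6148 had an unadjusted p under 0.05.

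Of 31 tested genes of disease-associated microglia, 26 rose, 1 fell and 4 did not pass, with 27 and 1 adjusted over the list alone (camera adjusted p = 2.9e-18, and adjusted p = 0.12 with an estimated correlation). Among them, Cd68 rose from 142 ± 18.9 to 1416 ± 169 (log2 3.31, adjusted p = 8.21e-07). Clec7a rose from 19.1 ± 5.9 to 451 ± 113 (log2 4.50, adjusted p = 8.93e-06) and Tyrobp, an adaptor of microglial receptors, from 179 ± 25.4 to 1611 ± 340.0 (log2 3.15, adjusted p = 7.11e-06). Homeostatic microglial genes were also higher, with 13 of 18 rising, none falling and 13 adjusted over the list alone (adjusted p = 0.27 with an estimated correlation). Hexb increased from 2380.1 ± 116 to 7199.5 ± 1522 and Cx3cr1 from 1189 ± 89.2 to 3219 ± 590.3. In the complement list 8 of 13 genes rose, none fell and 8 rose adjusted over the list alone (adjusted p = 0.12 with an estimated correlation). C1qa went from 952 ± 125 to 4557 ± 771 (log2 2.25, adjusted p = 2.12e-05). Of 17 genes of antigen presentation 12 rose and none fell, with 13 adjusted over the list alone (adjusted p = 0.13 with an estimated correlation). H2-K1 went from 568 ± 103 to 2425 ± 58.1 and B2m from 1404 ± 168 to 4189 ± 908. Type I interferon response genes rose in 18 of 21 cases, with 19 adjusted over the list alone and none falling (adjusted p = 0.13 with an estimated correlation). Ifitm3 went from 113 ± 51.3 to 471 ± 100.1 and Irf9 from 166 ± 1.5 to 404 ± 52.7. The inflammatory cytokine list, called cytokine genes below, also held receptor and signalling genes such as Tlr2 and Myd88. Its genes rose in 6 of 13 cases and fell in 1, with 8 and 1 adjusted over the list alone (adjusted p = 0.10 with an estimated correlation). Tlr2 went from 28.1 ± 21.2 to 231 ± 2.1. Over the alternatives the genes rising numbered 24 to 28 for disease-associated and 7 to 13 for homeostatic microglia, 7 to 9 for complement, 8 to 13 for antigen presentation, 10 to 19 for interferon and 3 to 8 for cytokines.

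Reactive astrocyte genes rose in 17 of 21 cases, none fell and 17 rose adjusted over the list alone (camera adjusted p = 2.9e-14, and adjusted p = 0.10 with an estimated correlation). Besides Gfap and C4b, Serpina3n, a secreted protease inhibitor, rose from 1107 ± 193 to 7042 ± 1148 (log2 2.67, adjusted p = 1.82e-05). The list of general astrocyte genes was not called (camera adjusted p = 0.29), with 5 of 15 genes rising and 1 falling, and 6 and 2 adjusted over the list alone. Lysosomal genes rose in 22 of 30 cases and none fell, with 22 and 1 adjusted over the list alone (adjusted p = 0.12 with an estimated correlation). The cathepsin genes Ctsz and Ctss went from 703 ± 124 to 2974 ± 486 and from 1381 ± 84.1 to 5326 ± 1236. The leukocyte gene Ptprc rose from 78.2 ± 14.9 to 329.9 ± 72 (log2 2.06, adjusted p = 0.000196), while Hbb-bs did not pass (log2 1.31, adjusted p = 0.326, and 2.39 and 0.0416 without 5xFAD vehicle 2, with a log2 of -0.86 without 5xFAD vehicle 1 and 3).

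Some neuronal genes were lower in 5xFAD than in nTg hippocampus, 13 of 27 presynaptic, 15 of 22 postsynaptic, 9 of 22 glutamate receptor, 12 of 21 GABA and 16 of 37 calcium-signalling genes. None of these lists was called with an estimated correlation. Over the alternatives run, the genes falling numbered 6 to 19 for presynaptic, 12 to 16 for postsynaptic, 5 to 11 for glutamate receptor, 8 to 14 for GABA and 12 to 18 for calcium-signalling genes. Gabrb2 (ENSMUSG00000007653), a subunit of the GABA-A receptor, fell from 3230.2 ± 234 to 1317 ± 72.6 normalised reads (SD, n = 3, log2 -1.29, adjusted p = 0.000182). Grm5 (ENSMUSG00000049583), a metabotropic glutamate receptor, fell from 8381 ± 529.8 to 4053 ± 177 (log2 -1.05, adjusted p = 0.000232), and Homer1 (ENSMUSG00000007617), a postsynaptic scaffold, from 3297 ± 156 to 1825 ± 152 (log2 -0.86, adjusted p = 0.000401). Of 22 postsynaptic scaffold genes 15 fell, none rose and 15 fell adjusted over the list alone (camera adjusted p = 1.2e-08, and adjusted p = 0.12 with an estimated correlation), Nlgn1 among them (2187 ± 86.3 to 1254 ± 9). Presynaptic genes fell in 13 of 27 cases and rose in 1, with 15 and 1 adjusted over the list alone (adjusted p = 0.29 with an estimated correlation). The cell-adhesion gene Nrxn1 went from 13388 ± 83.2 to 7314 ± 829 and the vesicle gene Sv2b from 14004 ± 782 to 7275 ± 1069.6. Of 22 glutamate receptor genes 9 fell and 1 rose, with 11 and 1 adjusted over the list alone (adjusted p = 0.29 with an estimated correlation). Gria1 was 24416 ± 2129 against 14311 ± 742. Of 21 GABA and interneuron genes 12 fell, none rose and 12 fell adjusted over the list alone (adjusted p = 0.13 with an estimated correlation), with Gabrg2 at 4438 ± 162 against 2614 ± 68.8.

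Calcium-signalling and calcineurin genes fell in 16 of 37 cases and rose in 1, with 17 and 4 adjusted over the list alone (adjusted p = 0.14 with an estimated correlation). Plcb1, a phospholipase, went from 6319.7 ± 258 to 3174 ± 403 (adjusted p = 0.000232) and Atp2a2, the calcium pump of the endoplasmic reticulum, from 24819.5 ± 1009.9 to 14271 ± 1442 (log2 -0.80, adjusted p = 0.000401). CREB targets and immediate-early genes fell in 11 of 25 cases, with 12 adjusted over the list alone and none rising (adjusted p = 0.26 with an estimated correlation). Nr4a3 went from 2839 ± 313 to 1434 ± 296 and Bdnf from 1017 ± 119.8 to 609.9 ± 96.4, the latter not called with Kdm5d as a covariate (adjusted p = 0.056). Of 6 tested TRPC channel genes 3 fell, with 4 adjusted over the list alone and none rising (adjusted p = 0.26 with an estimated correlation). Trpc5 fell from 527 ± 41.4 to 183 ± 26.8 (log2 -1.53, adjusted p = 0.000757) and Trpc4 from 1336 ± 31.4 to 755 ± 36.2 (log2 -0.82, adjusted p = 0.00048). CA1 markers fell in 7 of 12 cases, with 8 adjusted over the list alone and none rising (adjusted p = 0.12 with an estimated correlation). Man1a went from 1992 ± 164 to 1189 ± 37.5 and Nr3c2 from 4517 ± 353 to 2334 ± 332. Dentate gyrus markers fell in 7 of 15 cases and rose in 1, with 9 and 1 adjusted over the list alone (adjusted p = 0.29 with an estimated correlation). Calb1 went from 2839 ± 186 to 1692 ± 163 and Sema5a from 2765 ± 198 to 1695 ± 121. Chaperone genes fell in 8 of 15 cases and rose in 2, with 9 and 2 adjusted over the list alone (adjusted p = 0.14 with an estimated correlation). Hspa4 and Hspd1 went from 6297 ± 305 to 3926 ± 221 and from 4209.5 ± 106 to 2701 ± 259. Over the alternatives the genes falling numbered 6 to 16 for CREB targets and immediate-early genes, 2 to 8 for dentate gyrus, 5 to 9 for CA1 and 6 to 12 for chaperones.

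Among genes that fell, Eno1b and Rpl37rt had the lowest log2 changes of the named genes, at -6.77 and -3.59. Both are near-identical copies of other genes, so the reads behind them may be shared with those genes and their values are uncertain. The Eno1b call ended without nTg vehicle 1 or 2 or without 5xFAD vehicle 1 or 3, with adjusted p between 0.0529 and 0.0685, and its log2 change was -0.84 without 5xFAD vehicle 1 and 3. EdgeR did not call Eno1b (adjusted p = 0.181). Markers of tissue next to the hippocampus were not called as groups by camera in this comparison. Choroid plexus had 0 of 15 genes passing, ependyma 1 of 10, and striatum and hypothalamus 1 of 12. Thalamus had 1 rising and 2 falling of 13, and neocortex 1 rising and 1 falling of 15. The choroid plexus median log2 ranged from -0.61 to 0.98 over the alternatives, so a shift of that list is not excluded.

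The tests were limma on log2 values and camera over 41 gene lists, of which 26 were called in this comparison and 0 with an estimated correlation, where 14 had an unadjusted p under 0.05. Fry called 23. The count of 4249 genes became 1867 with the log2 value of Kdm5d as a covariate, 1579 without 5xFAD vehicle 1 and 3, and 2803 without nTg vehicle 3. Under upper-quartile scaling, which moved the median of all genes to 0.101 on the log2 scale from 0.024, 2539 genes rose and 1682 fell, and with a trend over GC content and transcript length removed 1462 rose and 3004 fell.

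**Figure D2:**
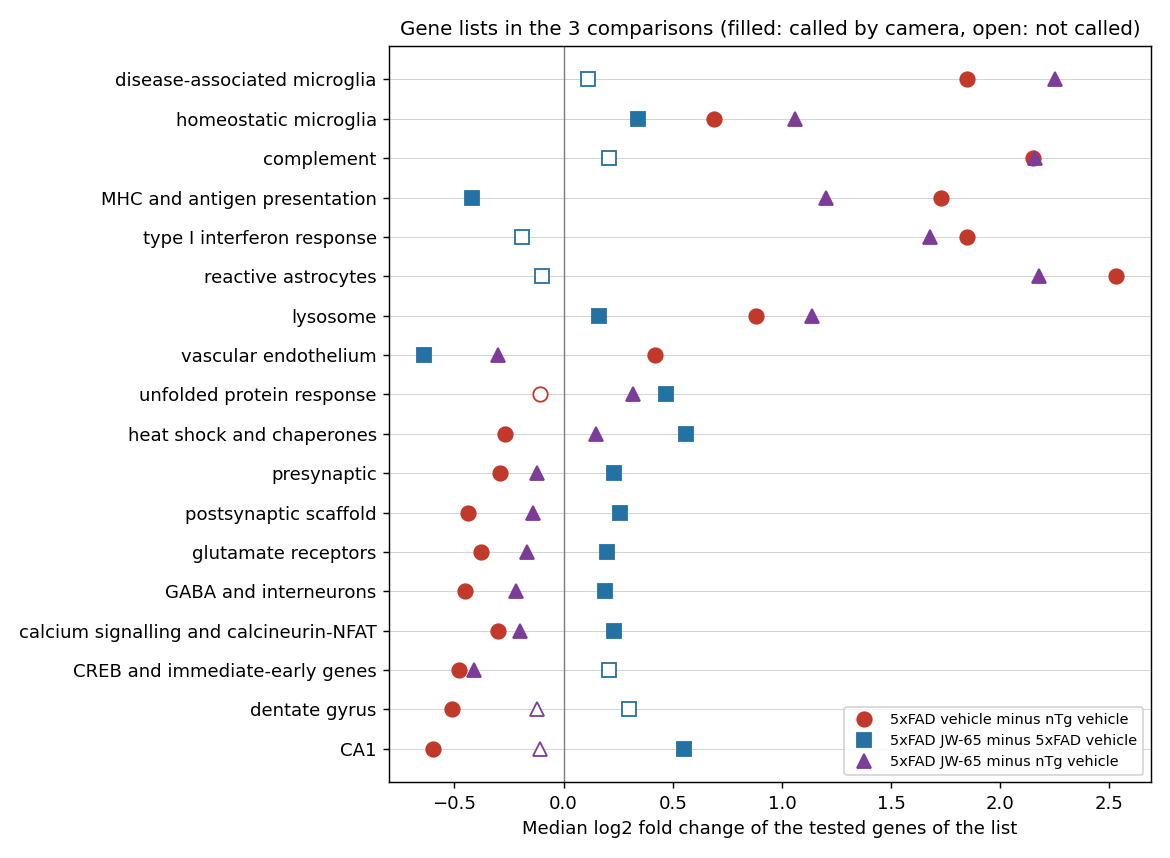
Median log2 fold change of the tested genes of 18 gene lists (x axis) in the comparisons of 5xFAD vehicle with nTg vehicle (circles), 5xFAD JW-65 with 5xFAD vehicle (squares) and 5xFAD JW-65 with nTg vehicle (triangles), with filled symbols for lists called by camera. Disease-associated microglia lie at 1.85, 0.11 and 2.25 in these comparisons, and heat shock and chaperone genes at -0.27, 0.56 and 0.15.

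The comparison of JW-65 with vehicle within 5xFAD mice shows how the hippocampus differed after the TRPC3 antagonist. Under JW-65, 11 of 15 chaperone genes, 10 of 23 genes of the unfolded protein response and a minority of synaptic genes (4 of 27 presynaptic and 6 of 22 postsynaptic) were higher, and 5 of 15 vascular endothelial genes were lower. No list was called with an estimated correlation. Over the alternatives run, the genes passing numbered 4 to 11 for chaperones, 4 to 13 for the unfolded protein response, 1 to 9 for presynaptic, 0 to 9 for postsynaptic and 1 to 8 for vascular genes. Hspa4 (ENSMUSG00000020361), a cytosolic chaperone, rose 1.59-fold, from 3926 ± 221 to 6258 ± 457 normalised reads (SD, n = 3, adjusted p = 0.00596). Hspa5 (ENSMUSG00000026864), the main chaperone of the endoplasmic reticulum, rose 1.91-fold, from 4288 ± 957 to 8056 ± 516 (adjusted p = 0.0098). Of 15090 genes tested, 1254 changed, of which 732 rose and 522 fell, and 4037 had an unadjusted p under 0.05.

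Of 15 heat shock and chaperone genes 11 rose, none fell and 11 rose adjusted over the list alone (camera adjusted p = 2.6e-09, and adjusted p = 0.14 with an estimated correlation). Dnaja1 rose from 4781 ± 186 to 7344 ± 245 (log2 0.62, adjusted p = 0.00583) and Hspa4l from 2645 ± 191 to 4896 ± 1075 (log2 0.87, adjusted p = 0.0119). Hspa8 went from 20972 ± 1131 to 31748 ± 1872 (log2 0.60, adjusted p = 0.00978). Its retrocopy Gm15459, whose reads could be shared with Hspa8, was listed at 3.6 in 5xFAD vehicle 1 and at 9644.5 or more in the other 8 libraries, so the Hspa8 value is uncertain. Of 23 genes of the unfolded protein response 10 rose and none fell, with 16 adjusted over the list alone (camera adjusted p = 4.5e-09, and adjusted p = 0.18 with an estimated correlation). Hsp90b1 rose from 5313 ± 469 to 8792 ± 439.6 (log2 0.73, adjusted p = 0.00583). Pdia3, a protein disulfide isomerase, rose from 3394 ± 169 to 5046 ± 149 (log2 0.57, adjusted p = 0.00681) and Calr from 6212 ± 835 to 9764 ± 404 (log2 0.66, adjusted p = 0.0098). The calls ended for Hspa4l without 5xFAD vehicle 1 and 3 (adjusted p = 0.0703) and for Calr without both libraries high in Kdm5d (0.051), with log2 changes of 0.7 to 1.08 and 0.5 to 0.84 over the alternatives.

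Postsynaptic scaffold genes rose in 6 of 22 cases, with 10 adjusted over the list alone and none falling (camera adjusted p = 6.3e-07, and adjusted p = 0.25 with an estimated correlation). Homer1 rose from 1825 ± 152 to 2922 ± 341 (log2 0.68, adjusted p = 0.0102) and Lrrtm1 from 1695 ± 34.5 to 2526 ± 123 (log2 0.57, adjusted p = 0.0119). Presynaptic genes rose in 4 of 27 cases, with 9 adjusted over the list alone and none falling (adjusted p = 0.63 with an estimated correlation). Nrxn1 rose from 7314 ± 829 to 11132 ± 1170.0 (adjusted p = 0.0119) and Sv2b from 7275 ± 1069.6 to 11107 ± 988 (adjusted p = 0.0151), the latter not without 5xFAD JW-65 3 (adjusted p = 0.054). Of 22 glutamate receptor genes 3 rose, with 5 adjusted over the list alone and none falling (adjusted p = 0.63 with an estimated correlation). Grm5 went from 4053 ± 177 to 6560.5 ± 1036 and Gria1 from 14311 ± 742 to 20742 ± 923. Of 21 GABA and interneuron genes 4 rose and none fell, with 10 and 1 adjusted over the list alone (adjusted p = 0.59 with an estimated correlation). Gabrb2 was 1317 ± 72.6 under vehicle and 2389 ± 488 under JW-65 (log2 0.84, adjusted p = 0.0119). CA1 markers rose in 5 of 12 cases, with 7 adjusted over the list alone and none falling (adjusted p = 0.25 with an estimated correlation). Man1a went from 1189 ± 37.5 to 1980.1 ± 78.8. Gpr161, an orphan receptor, rose by 0.90 on the log2 scale (adjusted p = 0.0134). Camera did not call dentate gyrus markers (1 of 15 rising, adjusted p = 0.091), CA3 and CA2 markers (2 of 19 rising, 0.083) or CREB targets and immediate-early genes (4 rising and 1 falling of 25, 0.22). The calls on Lrrtm1, Sv2b and Gpr161 ended without both libraries high in Kdm5d, and that on Sv2b also when only the groups compared were fitted. Without 5xFAD vehicle 1 and 3 (a fit that kept 1 vehicle library) the calls on Homer1, Lrrtm1, Nrxn1, Sv2b, Grm5, Gria1, Gabrb2 and Gpr161 ended. Over all alternatives, that fit included, their log2 changes lay between 0.56 and 0.85 (Homer1), 0.52 and 0.70 (Lrrtm1), 0.44 and 0.74 (Nrxn1), 0.45 and 0.71 (Sv2b), 0.56 and 0.85 (Grm5), 0.32 and 0.58 (Gria1), 0.69 and 1 (Gabrb2) and 0.61 and 1.02 (Gpr161). The genes rising over the alternatives numbered 0 to 5 for glutamate receptors, 0 to 8 for GABA and 2 to 7 for CA1.

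Of 37 calcium-signalling and calcineurin genes 8 rose and 1 fell, with 12 and 1 adjusted over the list alone (camera adjusted p = 0.0018, and adjusted p = 0.30 with an estimated correlation). Atp2a2 rose from 14271 ± 1442 to 21609.5 ± 1523 (log2 0.60, adjusted p = 0.0119) and Camk4, a calcium-dependent kinase, from 434 ± 16.2 to 718 ± 129 (log2 0.71, adjusted p = 0.0158, and 0.71 and 0.0527 without 5xFAD vehicle 3). Itpr3, a calcium-release channel, fell from 202 ± 23.3 to 95.3 ± 5 (adjusted p = 0.0157), a call that ended without 5xFAD vehicle 3 (0.0594) or 5xFAD JW-65 2 (0.0559). The list of TRPC channels was not called (camera adjusted p = 0.091), with 2 of 6 genes rising and 1, Trpc3, falling, and the same counts adjusted over the list alone. Trpc5 rose from 183 ± 26.8 to 465 ± 130.3 (log2 1.31, adjusted p = 0.0119) and Trpc4 from 755 ± 36.2 to 1040.0 ± 118 (adjusted p = 0.0279). The Trpc4 call ended without 5xFAD vehicle 1 or 3 or 5xFAD JW-65 2 or 3 (adjusted p between 0.0594 and 0.0954). Fitting only the groups compared ended the calls on Camk4 and Trpc4. Leaving out both libraries high in Kdm5d ended those on Itpr3 and Trpc4. Without 5xFAD vehicle 1 and 3 together none of Atp2a2, Camk4, Itpr3, Trpc5 and Trpc4 was called. Over all alternatives their log2 changes lay between 0.4 and 0.67 (Atp2a2), 0.57 and 0.85 (Camk4), -1.16 and -0.88 (Itpr3), 1.17 and 1.66 (Trpc5) and 0.37 and 0.52 (Trpc4). The calcium-signalling genes rising numbered 1 to 12.

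Vascular endothelial genes fell in 5 of 15 cases, with 9 adjusted over the list alone and none rising (camera adjusted p = 1.4e-06, and adjusted p = 0.30 with an estimated correlation). Slco1a4 (ENSMUSG00000030237), a transporter of the blood-brain barrier, fell from 815 ± 147 to 375 ± 9.2 (log2 -1.10, adjusted p = 0.00583), against 609 ± 24.5 in nTg. Vwf, von Willebrand factor, fell from 1087 ± 186 to 211 ± 29.3 (log2 -2.36, adjusted p = 0.0171), and its call ended without 5xFAD vehicle 3, 5xFAD JW-65 2 or 5xFAD JW-65 3 (adjusted p between 0.0538 and 0.0619) or without 5xFAD vehicle 1 and 3 together (0.167), with log2 changes between -2.51 and -2.21 over the alternatives. Haemoglobin transcripts were highest in the same 5xFAD vehicle group without passing the test (Hbb-bs log2 -2.12, adjusted p = 0.178). Without 5xFAD vehicle 2 Hbb-bs was called lower under JW-65 (log2 -3.21, adjusted p = 0.0237), while without 5xFAD vehicle 1 and 3 its log2 change was 0.05.

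Disease-associated microglia were not called as a list (camera adjusted p = 0.13), with 2 of 31 genes rising, none falling and 1 rising adjusted over the list alone. The 2 were Ctsd, a lysosomal protease (28118 ± 7181 to 46342 ± 6322, adjusted p = 0.026), and Lpl, lipoprotein lipase (1997 ± 39.3 to 2954 ± 232, adjusted p = 0.0465). Reactive astrocyte genes were not called either (camera adjusted p = 0.76), with 0 of 21 rising and 1, C4b, falling, and 0 adjusted over the list alone. C4b went from 19194 ± 2678 to 13878 ± 1340.4 (log2 -0.46, adjusted p = 0.0441), and Gfap was 75225 ± 21727 under vehicle and 101153 ± 10017 under JW-65 (log2 0.46, adjusted p = 0.127). Without 5xFAD vehicle 2 Gfap was called higher under JW-65 (log2 0.68, adjusted p = 0.0108), while without 5xFAD vehicle 1 and 3 its log2 change was 0.03. Homeostatic microglia were called upward with 1 of 18 genes, Selplg, rising and 0 adjusted over the list alone (camera adjusted p = 0.0088, and adjusted p = 0.63 with an estimated correlation). The median log2 of the homeostatic microglia list was 0.34, 0.13 without 5xFAD vehicle 3 and 0.02 without 5xFAD vehicle 1 and 3. Antigen presentation was called downward with 1 of 17 genes, H2-Q7, falling and 3 adjusted over the list alone (camera adjusted p = 0.022, and adjusted p = 0.63 with an estimated correlation). The water channel gene Aqp4 of astrocytes rose from 5048 ± 984 to 7992 ± 151 (log2 0.68, adjusted p = 0.0139). Without single libraries the calls on C4b (8 of the 9 fits, all but that without 5xFAD vehicle 1, adjusted p between 0.0517 and 0.135) and Selplg (8 fits, all but that without 5xFAD vehicle 2, 0.0512 to 0.13) ended. So did those on Lpl (7 fits, all but those without nTg vehicle 2 or 3, 0.0514 to 0.128), H2-Q7 (5 fits, without 5xFAD vehicle 1 or 3 or any JW-65 library, 0.0594 to 0.0965) and Ctsd (4 fits, without 5xFAD vehicle 1 or 3 or 5xFAD JW-65 1 or 2, 0.057 to 0.0835). Without 5xFAD vehicle 1 and 3 together these 5 calls ended, as did that on Aqp4. The Aqp4 call also ended without both libraries high in Kdm5d. Over all alternatives the log2 changes lay between -0.65 and -0.37 (C4b), 0.5 and 1.01 (Selplg), 0.49 and 0.63 (Lpl), -1.21 and -0.8 (H2-Q7), 0.38 and 0.93 (Ctsd) and 0.38 and 0.83 (Aqp4).

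Among single genes with large changes, Epha6, an ephrin receptor, rose from 481 ± 80.2 to 1164 ± 223 (log2 1.27, adjusted p = 0.00711), and Sstr4, a somatostatin receptor, from 246 ± 23 to 543 ± 35.1 (log2 1.14, adjusted p = 0.00583). Wnt10b, a secreted signalling protein, fell from 136 ± 38.2 to 12.6 ± 3.2 (log2 -3.32, adjusted p = 0.00583), close to its 12.4 ± 5.2 in nTg, and Ovgp1 from 263 ± 72.5 to 58.6 ± 22.5 (log2 -2.18, adjusted p = 0.01). Uimc1, with the highest log2 change of the named genes, went from 459 ± 304 to 1575 ± 28.3 (log2 2.08, adjusted p = 0.0233). This became 1.37 without 5xFAD vehicle 1 and lost its call without any single JW-65 library (adjusted p between 0.066 and 0.0715). Without 5xFAD vehicle 1 and 3 the calls on Wnt10b (0.0677, log2 -3.49 to -2.94 over the alternatives) and Ovgp1 (0.102, -2.46 to -1.91) ended.

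Of the 41 lists camera called 15, with 0 called under an estimated correlation (5 at an unadjusted p under 0.05), 9 after quantile normalization and 7 by fry. The count of 1254 genes became 307 when only the 6 libraries compared were fitted, 824 with replicate number as a block, 832 with Ttr as a covariate, 2372 by DESeq2 and 2404 at an adjusted p under 0.1. Without single libraries it was 810 (nTg vehicle 1), 620, 2456 and 292 (5xFAD vehicle 1, 2 and 3) and 433, 361 and 376 (5xFAD JW-65 1, 2 and 3), and it was 210 without both libraries high in Kdm5d and 157 without 5xFAD vehicle 1 and 3. Under upper-quartile scaling 560 genes rose and 633 fell, and 1190 rose and 540 fell with the GC and length trend removed.

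**Figure D3:**
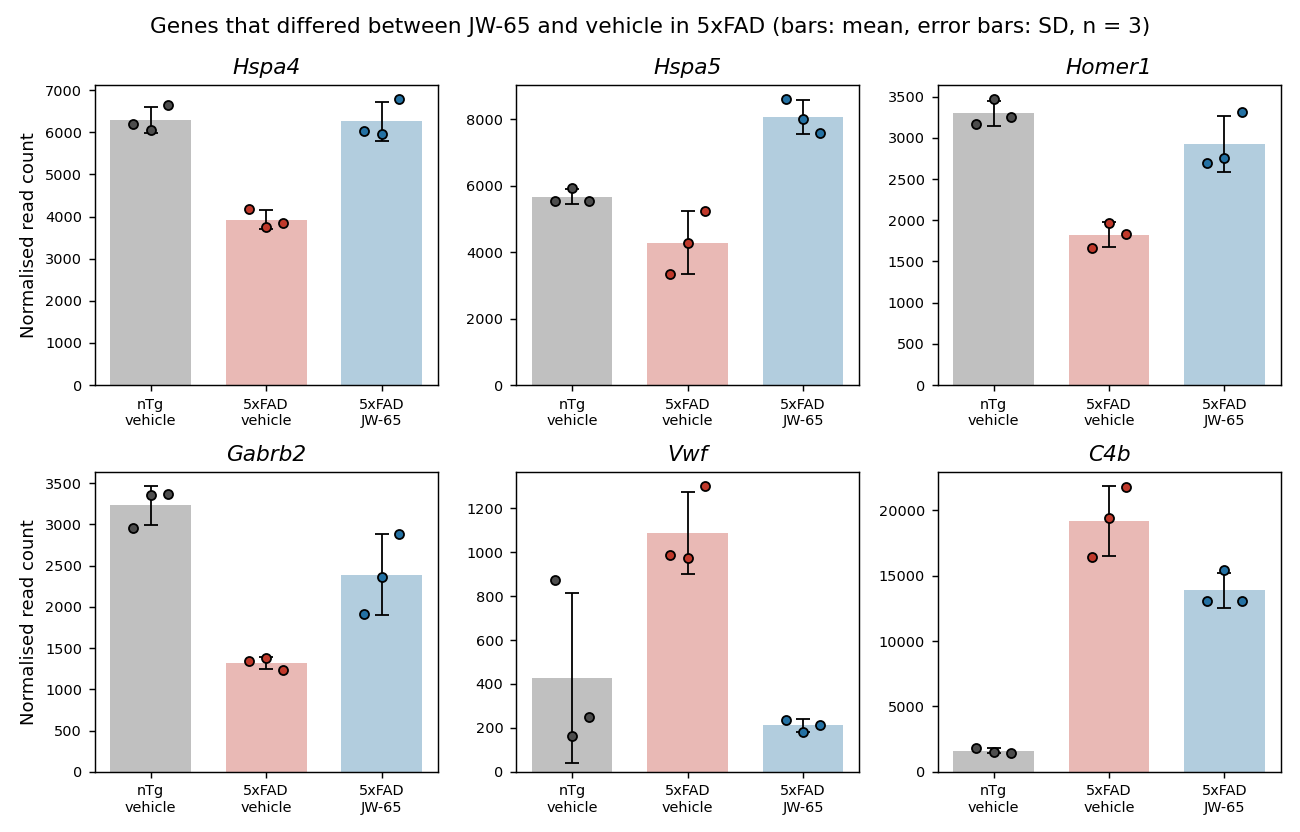
Normalised read counts of Hspa4, Hspa5, Homer1, Gabrb2, Vwf and C4b in each library (points), with the group mean (bars, axes starting at 0) and SD (error bars, n = 3). Hspa4 lies at 6297 ± 305 in nTg, 3926 ± 221 in 5xFAD vehicle and 6258 ± 457 in JW-65, and the 3 JW-65 libraries of C4b lie below all 5xFAD vehicle libraries.

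The comparison of JW-65-treated 5xFAD with nTg mice asks which differences remained under treatment. Many microglial, reactive astrocyte, complement and lysosomal genes were above nTg, while fewer synaptic genes were lower than in the vehicle comparison, a difference in counts that was not itself tested. Clec7a (ENSMUSG00000079293), a pattern-recognition receptor, stood at 622 ± 124 against 19.1 ± 5.9 normalised reads in nTg (SD, n = 3, log2 4.98, adjusted p = 2.76e-06). Of 15090 genes tested 946 changed, of which 726 rose and 220 fell, and 3324 had an unadjusted p under 0.05.

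Disease-associated microglial genes rose in 25 of 31 cases and none fell, with 28 adjusted over the list alone (camera adjusted p = 2.4e-36, and adjusted p = 0.029 with an estimated correlation). Tyrobp stood at 2226 ± 364 against 179 ± 25.4 and Cd68 at 1501 ± 174 against 142 ± 18.9. Reactive astrocyte genes rose in 16 of 21 cases, complement genes in 8 of 13, lysosomal genes in 20 of 30 and inflammatory cytokine genes in 5 of 13, with 17, 9, 23 and 8 adjusted over the list alone, none falling and an adjusted p = 0.029 with an estimated correlation for each. Gfap was 101153 ± 10017 against 11765 ± 1089.5 (log2 3.10, adjusted p = 3.96e-06), C4b 13878 ± 1340.4 against 1599 ± 187 (log2 3.12, adjusted p = 6e-07) and Ctsd 46342 ± 6322 against 7659 ± 573 (log2 2.59, adjusted p = 9.39e-06). General astrocyte genes rose in 7 of 15 cases and none fell, with a median log2 of 0.26 and 7 rising and 1 falling adjusted over the list alone (camera adjusted p = 0.019, and adjusted p = 0.49 with an estimated correlation). Homeostatic microglial genes rose in 13 of 18 cases, antigen presentation genes in 10 of 17 and interferon response genes in 13 of 21, with 13, 11 and 17 adjusted over the list alone, none falling and an adjusted p = 0.097 with an estimated correlation for each. Hexb was 9212 ± 1047 against 2380.1 ± 116, H2-K1 1759 ± 132 against 568 ± 103 and Ifit3 459.6 ± 43.2 against 179 ± 30.5. Over the alternatives 2 to 7 general astrocyte, 3 to 8 cytokine, 7 to 11 antigen presentation and 9 to 15 interferon genes rose.

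The unfolded protein response was called upward in JW-65 against nTg, with 8 of 23 genes rising, 10 adjusted over the list alone and none falling (camera adjusted p = 5.6e-06, and adjusted p = 0.097 with an estimated correlation). Sdf2l1 stood at 556 ± 112 against 171 ± 10.7 (log2 1.68, adjusted p = 0.000438) and Calr at 9764 ± 404 against 6664 ± 96.2 (log2 0.55, adjusted p = 0.00631). Of 15 chaperone genes 4 rose and none fell, with 5 adjusted over the list alone (adjusted p = 0.22 with an estimated correlation), including Cryab (2576 ± 212 against 1619 ± 158), which was not called with the GC and length trend removed (log2 0.41, adjusted p = 0.0875). No presynaptic gene of 27 and no glutamate receptor gene of 22 passed in limma, nor did any adjusted over the list alone, with 7 and 6 at an unadjusted p under 0.05, although camera called both lists downward (adjusted p = 0.021 and 0.046, and adjusted p = 0.52 and 0.49 with an estimated correlation). Postsynaptic scaffold genes fell in 2 of 22 cases, with 3 adjusted over the list alone and none rising (adjusted p = 0.26 with an estimated correlation). GABA and interneuron genes fell in 4 of 21, with 6 adjusted over the list alone and none rising (adjusted p = 0.12 with an estimated correlation). Immediate-early genes fell in 3 of 25 cases, with 9 adjusted over the list alone and none rising (adjusted p = 0.25 with an estimated correlation), among them Egr1 (2260.4 ± 560.2 against 4212 ± 378, adjusted p = 0.012), whose call ended without nTg vehicle 2 or 5xFAD JW-65 1 or 2 (adjusted p between 0.0522 and 0.0544) or with Kdm5d as a covariate (0.0648) or without both libraries high in Kdm5d, with log2 changes of -1.11 to -0.75 over the alternatives. Of the 6 TRPC channel genes 0 passed, with 1 at an unadjusted p under 0.05 and 1 falling adjusted over the list alone (camera adjusted p = 0.13), and Trpc5 was 465 ± 130.3 against 527 ± 41.4 (adjusted p = 0.595). Ints6, a subunit of the integrator complex, fell to 464 ± 132 from 1303 ± 94.4 (log2 -1.52, adjusted p = 0.000872), and the mitochondrial gene mt-Nd3 to 6860.0 ± 1364 from 20032 ± 582 (log2 -1.57, adjusted p = 0.00786). Over the alternatives the genes falling numbered 0 to 11 for immediate-early genes, 0 to 7 for postsynaptic, 0 to 5 for GABA, 0 to 4 for presynaptic and 0 to 2 for glutamate receptor genes. Those rising numbered 3 to 10 for the unfolded protein response and 1 to 5 for chaperones.

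Camera called 27 of 41 lists, 8 with an estimated correlation and 16 by fry. Neocortex markers were among the 27, called downward with 1 of 15 genes falling (camera adjusted p = 0.022, and adjusted p = 0.4 with an estimated correlation). The count of 946 genes became 2145 with array quality weights, 1442 when only the 6 libraries compared were fitted, 1655 by DESeq2, 1602 at an adjusted p under 0.1, 500 with Kdm5d as a covariate, 544 without both libraries high in Kdm5d and 1430 without 5xFAD vehicle 1 and 3. Without single libraries it was 549 and 558 (nTg vehicle 2 and 3) and 514 and 444 (5xFAD JW-65 1 and 2). The split of 726 rising and 220 falling became 408 and 36 without 5xFAD JW-65 2, 506 and 52 without nTg vehicle 3, and 1238 and 907 with array quality weights.

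Of the 4249 genes that differed between the vehicle groups, 958 changed in the opposite direction under JW-65. Of the 2048 genes higher in 5xFAD vehicle, 343 fell under JW-65 and 13 rose, and of the 2201 lower genes, 615 rose and none fell. Epha6, for example, was 1428 ± 191 in nTg, 481 ± 80.2 in 5xFAD vehicle and 1164 ± 223 under JW-65. Against nTg, JW-65 left 622 of the 2048 higher genes and 158 of the 2201 lower genes changed the same way. A further 1424 and 2040 did not pass, which does not show that they returned to the nTg level. The median log2 difference from nTg was 0.89 under vehicle and 0.44 under JW-65 for the higher genes. For the lower genes it was -0.53 and -0.22. These counts and medians cover genes picked for their difference under vehicle, which favours a smaller difference in any other group.

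The 958 genes that moved back share the 5xFAD vehicle libraries between both comparisons, which pushes the fold changes in opposite directions with no effect at all. Independent lists of these sizes would share 70.8 genes that rose and then fell, 106.8 that fell and then rose, 99.3 that rose in both and 76.1 that fell in both. Simulated unchanged groups that share the vehicle libraries gave a mean of 0.01 such genes, a value near 0 because unchanged groups call almost no genes in either comparison. They gave a correlation of the fold changes across genes of -0.5 against the observed -0.609, and a covariance of -0.0387 against -0.175, a difference of -0.137. A further simulation, chosen after the results had been seen, kept the fitted difference between the vehicle groups and gave JW-65 no effect. It called 5564.05 genes between the vehicle groups on average, against the 4249 observed. Between JW-65 and 5xFAD vehicle it called a mean of 0.15 genes, against 1254. A mean of 0.07 genes (2 at most) was called in opposite directions. This is near 0 because almost no gene was called under JW-65, so this count says nothing about the 958. The correlation of the fold changes was -0.199 against the observed -0.609, and the covariance was -0.0385. Both simulations drew independent genes. The 3 vehicle libraries could not give each comparison replicates of its own. Part of the excess may therefore come from the shared libraries. Genes are not independent replicates in these correlations. In a second estimate the genes were chosen with 2 of the 3 5xFAD vehicle libraries, and JW-65 was compared with the library held out. The mean shift of these genes was 37.8%, 28.7% and 41% of the way to nTg for the 3 held-out libraries. The mean was 35.9% ± 6.4 (SD, n = 3), with 24.5% ± 3.8 for genes higher in 5xFAD and 54.1% ± 9.9 for genes lower in 5xFAD. The 3 estimates reuse the same JW-65 and nTg libraries and overlapping pairs of vehicle libraries, so they are not independent. Across the 3 groups together 3839 genes differed by limma's F test, and 6063 had an unadjusted p under 0.05.

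The count of 958 became 240 when only the groups compared were fitted, 634 with Ttr and 593 with Kdm5d as a covariate, 188 without both libraries high in Kdm5d, 121 without 5xFAD vehicle 1 and 3, 1723 by DESeq2 and 1802 at an adjusted p under 0.1. Leaving out single libraries gave 556, 596 and 597 (nTg vehicle 1, 2 and 3), 495, 1963 and 234 (5xFAD vehicle 1, 2 and 3) and 389, 304 and 274 (5xFAD JW-65 1, 2 and 3). The F test count became 1791 with Kdm5d as a covariate, 2409 without both libraries high in Kdm5d and 1896 without 5xFAD vehicle 1 and 3, and 2508 and 2365 without nTg vehicle 2 and 3 and 2507 without 5xFAD vehicle 3. Upper-quartile scaling gave 455 genes that rose and then fell beside 461 that fell and then rose, and 348 beside 1034 with the GC and length trend removed.

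**Figure D4:**
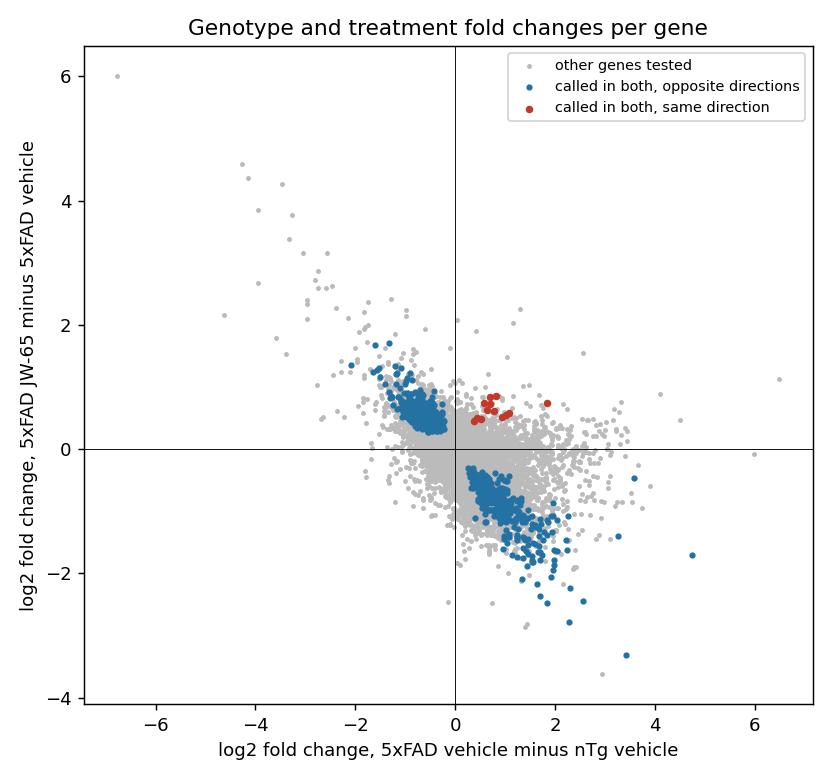
Log2 fold change of each tested gene in 5xFAD vehicle minus nTg vehicle (x axis) and in 5xFAD JW-65 minus 5xFAD vehicle (y axis), with genes called in both comparisons coloured by whether the directions are opposite or the same. The 958 genes called in opposite directions and the 13 called in the same direction are coloured, and both axes share the 5xFAD vehicle libraries.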

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

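Some fits were added after the data had been seen. These had Kdm5d as a covariate, or left out both libraries high in Kdm5d (5xFAD vehicle 1 and JW-65 1). Others left out 5xFAD vehicle 1 and 3, removed the GC and length trend, or used protein-coding nuclear genes alone. 5xFAD vehicle 1 and 3 were the libraries furthest from nTg on the first principal component. Array quality weights were instead lowest for 5xFAD vehicle 2, at 0.44 against 0.78 and 0.94 for 5xFAD vehicle 1 and 3. The planned covariate Xist was not run, since the table has no Xist value. The fit without 5xFAD vehicle 1 and 3 leaves 1 library in that group, which is assumed to vary like the other groups. Leaving out 1 library at a time gave 2803 to 4955 genes for 5xFAD vehicle against nTg vehicle, 292 to 2456 for JW-65 against 5xFAD vehicle, 444 to 1244 for JW-65 against nTg vehicle, 2365 to 4758 for the F test and 234 to 1963 for genes that moved back. In that order, the Kdm5d covariate gave 1867, 1010, 500, 1791 and 593 genes, and leaving out 5xFAD vehicle 1 and 3 gave 1579, 157, 1430, 1896 and 121. Leaving out both libraries high in Kdm5d gave 210 for JW-65 against 5xFAD vehicle, 544 against nTg, 2409 for the F test and 188 for genes moved back. Fitting only the groups compared gave 307, 1442 and 240 for JW-65 against 5xFAD vehicle, JW-65 against nTg and genes moved back, DESeq2 2372, 1655 and 1723, and an adjusted p under 0.1 2404, 1602 and 1802. The Ttr covariate gave 832 and 634 for JW-65 against 5xFAD vehicle and genes moved back, and array weights 2145 for JW-65 against nTg. With replicate number as a block, JW-65 against 5xFAD vehicle gave 824, but the numbers do not pair the libraries, since deviations of libraries with the same number correlated across groups at -0.09 to 0.07. Gene lists called numbered 0, 0 and 8 with an estimated correlation for the 3 comparisons, 9 after quantile normalization and 7 by fry for JW-65 against 5xFAD vehicle, and 16 by fry for JW-65 against nTg. DESeq2 called 1250 of the 1254 genes of JW-65 against 5xFAD vehicle and edgeR 1234, in the same direction. Of the genes named as called, 45 of 49 between the vehicle groups, 11 of 39 in JW-65 against 5xFAD vehicle and 21 of 24 in JW-65 against nTg were called in every fit run, and none reversed direction in any fit run. Under these fits the median of the blood cell list between the vehicle groups went from 1.3 to -0.15 without 5xFAD vehicle 1 and 3, and that of the lysosome list in JW-65 against 5xFAD vehicle from 0.16 to -0.01. For the same comparison, immediate-early genes went from 0.21 to -0.14 without 5xFAD vehicle 2 and reactive astrocytes from -0.1 to 0.02 without 5xFAD vehicle 3. With the GC and length trend removed, ribosomal proteins in JW-65 against nTg went from 0.19 to -0.02 and myelinating oligodendrocytes between the vehicle groups from 0.19 to -0.01. The cause of these differences was not tested.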

Other observations

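Of 49 genes of cytosolic ribosomal proteins 19 rose in 5xFAD against nTg under vehicle, 24 adjusted over the list alone, and none fell (camera adjusted p = 1.5e-06, and adjusted p = 0.49 with an estimated correlation). Their median log2 of 0.35 became 0.01, with 6 rising, once the GC and length trend was removed. Fau rose from 3274 ± 60.5 to 5512 ± 139.6 normalised reads (SD, n = 3, log2 0.75, adjusted p = 0.000708) and Rps19 from 2154 ± 96.3 to 4104 ± 121 (log2 0.93, adjusted p = 0.000832). Under JW-65 against vehicle the list was called downward with 1 of 49 genes, Rpl5, falling from 1057 ± 186 to 612 ± 49, a call that ended without both libraries high in Kdm5d (0.0697) (camera adjusted p = 0.0058, and adjusted p = 0.81 with an estimated correlation). Replication-dependent histone genes rose in 3 of 5 cases between the vehicle groups, with 5 adjusted over the list alone (adjusted p = 0.12 with an estimated correlation), and in 4 of 5 between JW-65 and nTg (adjusted p = 0.036 with an estimated correlation). H1f2 stood at 278 ± 67.4 in nTg, 599 ± 164 in 5xFAD vehicle and 692 ± 28.5 under JW-65, and its call between the vehicle groups ended without 5xFAD vehicle 1 and 3 (adjusted p = 0.135) or with Kdm5d as a covariate, with log2 changes of 0.61 to 1.33 over the alternatives. Genes of disease-associated oligodendrocytes, several of them shared with the microglial and astrocytic lists, rose in 9 of 12 cases and fell in 1 between the vehicle groups (adjusted p = 0.065 with an estimated correlation), and rose in 9 between JW-65 and nTg (adjusted p = 0.015 with an estimated correlation).

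Cholesterol synthesis genes were called upward in all 3 comparisons, with 5, 0 and 4 of 19 genes rising (2 to 10 over the alternatives in the first) and 6, 0 and 13 adjusted over the list alone, where 1 also fell between the vehicle groups (adjusted p = 0.68, 0.77 and 0.25 with an estimated correlation). The median log2 of the cholesterol synthesis list went from 0.25 to 0.06 between the vehicle groups with the GC and length trend removed, and from 0.23 to 0.07 in JW-65 against 5xFAD vehicle without 5xFAD vehicle 3. Ldlr, the receptor of low-density lipoprotein, rose from 494 ± 23.8 in nTg to 896 ± 30.9 in 5xFAD vehicle (adjusted p = 0.000576). Of 15 vascular endothelial genes, 5 of which fell under JW-65 against vehicle, 7 rose in 5xFAD vehicle against nTg, 0 to 8 over the alternatives (camera adjusted p = 0.012, and adjusted p = 0.45 with an estimated correlation). JW-65 lay below nTg for the vascular endothelium list, with a median log2 of -0.30 (0 without 5xFAD JW-65 2) and 1 of 15 genes falling (camera adjusted p = 0.048, and adjusted p = 0.49 with an estimated correlation). Ly6a was 247 ± 11.5 in nTg, 386 ± 53.4 in 5xFAD vehicle and 299.7 ± 44.1 under JW-65, and its change between the vehicle groups (adjusted p = 0.0149) ended without 5xFAD vehicle 3 (0.0613) or without vehicle 1 and 3 (0.131), and also after quantile normalization or with Kdm5d as a covariate, with log2 changes of 0.48 to 0.71 over the alternatives. CA3 and CA2 markers fell in 6 of 19 cases (3 to 8 over the alternatives), with 8 adjusted over the list alone (adjusted p = 0.26 with an estimated correlation). The lists of mitochondrial-encoded and nuclear oxidative phosphorylation genes were not called in any of the 3 comparisons. Within the mitochondrial list mt-Co2 rose and mt-Nd3 fell between nTg and JW-65, mt-Co2 from 32380.2 ± 2439 to 74442 ± 22339.7 (adjusted p = 0.0174), which ended without any nTg library or without 5xFAD JW-65 1 or 3 (0.0546 to 0.0746).

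The counts over other splits of the libraries were planned, while the remaining tests below were chosen after the results had been seen. The 10 splits of 6 libraries are too few for a share under 0.05. The real splits called 4249, 1254 and 946 genes (5xFAD vehicle against nTg, JW-65 against 5xFAD vehicle and JW-65 against nTg) and the highest other split 0, 4 and 1, and in each the real split alone (1 of 10) reached its count. For gene lists the real splits called 26, 15 and 27 and the highest other split 23, 20 and 24, with 1, 3 and 1 of 10 splits giving as many. For JW-65 against 5xFAD vehicle, other splits therefore called as many lists as the real one. Of 100 splits of the 9 libraries 1, the real one, gave 3839 or more genes by the F test (highest other 1044). For genes moved back 1 of 100, the real one, gave 958 or more (highest other 368). These splits mix nTg with 5xFAD libraries, so they show only that the 9 libraries were not interchangeable. They do not test how libraries were assigned to JW-65 and vehicle within 5xFAD.

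Of the 4249 genes changed in 5xFAD vehicle, 958 were called the other way under JW-65 and 13 the same way. Chance values of the shared vehicle libraries alone would leave a held-out shift near 0. The mean held-out shift was 35.9% ± 6.4 (SD, n = 3). The 3 shifts reuse the same JW-65 and nTg libraries, so this SD leaves out the spread of those groups and gives no test against 0. A trend over GC content and transcript length was not the whole cause, since 87.8% (841 of 958) of the genes moved back stayed so once it was removed. Without the 2 libraries high in Y-linked transcripts the held-out shift was 28.8% and 37.4%, so they were not the whole cause, although the genes were then picked with a single 5xFAD vehicle library, assumed to vary like the other groups. An effect of JW-65 may explain the pattern and remains a hypothesis, and a difference between the animals or in the handling of the vehicle libraries, which stand furthest from nTg on the first principal component, was not tested.

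App and Psen1 were higher under JW-65 than under vehicle (Psen1 not without 5xFAD vehicle 1 and 3, adjusted p = 0.0677), and Thy1 did not pass. Over 3 rescalings of the libraries App changed by 0.61, 0.59 and 0.52 and Psen1 by 0.50, 0.47 and 0.43 (log2), so 0.43 was the lowest, while Thy1 gave 0.09, 0.06 and -0.19. Relative to the median presynaptic gene, which would carry a larger neuronal share, App changed by 0.43 (95% interval 0.29 to 0.58). Psen1 changed by 0.32 (0.13 to 0.5), the lower bound being 0.13. The CA1 list rose by a median log2 of 0.55, the dentate gyrus list by 0.30 and the CA3 and CA2 list by 0.17. A larger share of CA1 neurons was therefore not addressed by this comparison with presynaptic genes. More RNA from all transgene copies would raise the excess over nTg alike, but the JW-65 to vehicle ratio of that excess was 2.52 (1.56 to 3.47) for App, 1.9 (1.67 to 2.13) for Psen1 and 1.09 (0.78 to 1.41) for Thy1, on the premise from general knowledge that the transgenes contain Thy1 sequence. A change of the endogenous or human App and Psen1 transcripts could explain this and is a hypothesis, since human and mouse transcripts were not separated and transgene dosage of the animals was not known.

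A search for genes listed at or near 0 in a single library found 16 in 5xFAD vehicle 1. It found 3 in nTg vehicle 1, 1 in 5xFAD JW-65 1 and 0 in the other 6 libraries. Genes near 0 in more than 1 library could not be found this way. Parents of retrocopies were sought for the 16 alone, so the genes found in other libraries are not shown to be retrocopies. Lower depth of 5xFAD vehicle 1 is excluded, since 6 libraries had fewer reads. Of 15 copies with a parent gene in the table, the parent lay above the range of the other 8 libraries for 6, and parent plus copy lay within that range for 6, below it for 8 and above it for 1. Only Vcp-rs and Gm6472 had both a parent above the range and a sum within it. For Gm5898 the copy had a median of 79.7 in the other libraries against 2563.2 to 3653.5 at its parent, so its sum decides little. Reads of the copies counted at their parents may explain part of the list (6 sums within the range). Under the rule first applied, sums below the range for most pairs, the 8 of 15 would have excluded this explanation, and it stays open only under a rule tightened after these counts had been seen (an exact 95% interval above 50%). Of these 8, Gm4737, Csnk2a3 and Gm3375 had a parent above the range, while Gm11868, Gm14292, Gm10039, Gm15459 and Gm7049 did not. For Gm4737, at 0 there, the parent Ahcy stood at 649.4 against 17.2 to 59.1 in the other libraries. A sum below the range therefore does not by itself exclude shared reads for a pair.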
